A study of Equus caballus with 12 samples.

How the data were processed

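The series measured RNA of the amniotic membrane, the innermost of the foetal membranes, in mares with experimentally induced ascending placentitis and in mares that served as negative controls. Per the labels' protocols, placentitis was induced by placing Streptococcus equi subspecies zooepidemicus, suspended in Todd Hewitt broth, into the cervix, and the control mares received no inoculation. Per the same protocols, RNA was isolated with the RNeasy Mini Kit and libraries were made with the NEBNext Ultra RNA Library Prep Kit. Each of the 12 samples carries an identifier of its own, so the groups share no replicate numbers. The labels do not say in words that each identifier is a separate mare. If any are not, the p-values measure only the spread between these samples.

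The deposited table holds whole-number counts per gene, 1 column per library, with no normalization. The submitters' processing notes name FastQC 0.12.0, Trimmomatic 0.39, HISAT2 and the EquCab3.0 genome build, without saying what each was used for. The version of HISAT2, the program that counted reads, its annotation and its strand setting are not given in the sources used here. Reads that overlapping genes or near-identical copies could share may therefore have been counted for either, and genes of opposite strands at a position could not be told apart. No genome or annotation was used here, so positions of genes are not given.

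The table has 32004 rows, of which 8764 were 0 in every library and 15294 carry a LOC name in place of a gene symbol. Its names were used as deposited. A non-breaking space stood inside the name in 50 rows, and 46 of these names ended in decimals, so that a gene symbol could not be read from them with certainty. They were tested under the names as they stand and left out of the gene lists. Total counts per library ran from 33095353 to 56372634. Within a group, the 30 pairs of libraries differed by a chi-square of 86.7 to 630 per degree of freedom over genes, so within a group no library was a second copy of another; pairs between the groups were not compared. Means are in CPM, counts scaled to a common library size, computed here from these deposited counts with TMM-adjusted library sizes, and are given with the SD over libraries.

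The main comparison used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default low-count filter by group and robust dispersion estimates. The filter kept 16327 genes, which hold 99.94% of all counts. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 for the adjusted p. Log2 fold changes are placentitis minus control and are given with their SE. On counts simulated for placentitis against control over 16327 genes, edgeR recovered 43 of 100 genes changed 2-fold and 81 of 100 changed 4-fold, with 5 calls among 16097 unchanged genes. DESeq2 recovered 52 of 100 and 89 of 100 in the same counts, with 38 calls among the unchanged genes. Each simulated gene varied independently, without differences between libraries that genes share. The recovery and the calls of unchanged genes therefore need not hold for the real libraries.

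A total of 39 gene lists covered inflammation, hormones, matrix, metabolism and stress, signs of library quality and markers of the cell types that the membrane or adjoining tissue could hold. The 38 lists with at least 4 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, and adjusted over lists. In simulated placentitis against control over 16327 genes, a shift of 0.5 log2 units in the hypoxia and glycolysis list gave an adjusted p = 1.07e-09 for it, and 0 other lists passed. The simulated genes varied independently of each other. In the real libraries, splits into 6 and 6 other than that by group passed a median of 8 lists, so the simulated 0 does not carry over. Beside this stand camera with the correlation estimated from the residuals, fry in its directional and mixed forms, and an exact two-sided permutation test of each list's score, which is the mean log2 CPM of its tested members in a library, over all 924 assignments of 6 libraries to each group. The smallest p this permutation test can give is 0.00216. For single members the number past the threshold is also given after the p-values were adjusted over the list alone.

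The comparisons, the main test, the lists and the rule for naming genes were fixed before the data were examined. The rule takes, in each direction, genes with a symbol that pass the threshold, or where none passes the 5 with the smallest p, with a mean count of at least 20 and at least 5 placentitis libraries beyond the control median. It also takes, for each list without a passing member, the 2 members with the highest expression; these are printed for the lists that passed and for some of the others. Every other gene named below was chosen after its values were seen, most often because it passed the threshold when adjusted over its list alone.

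Sample identifiers start with a letter whose meaning the labels do not give. All 6 placentitis samples and 2 controls carry O, and the other 4 controls carry K or L. The letter was treated as a possible cohort: controls with O were tested against the other controls, and the main comparison was repeated within O and with the letter as a term. Also chosen at that stage were fits with DESeq2 size factors and upper-quartile scaling in edgeR, no filter, a filter of CPM above 1 in at least 6 libraries, dispersion without the robust option, DESeq2 1.42.0, limma-voom with sample quality weights, a surrogate variable from sva 3.50.0, and each library left out in turn. Added after seeing the data were fits without 3 libraries rich in vascular transcripts, with a vascular score as a term, by DESeq2 with the letter as a term or without those 3 libraries, and without genes near 0 in single libraries. The vascular score is the mean log2 CPM in a library over the tested members of the endothelium list and the smooth muscle and pericyte list together.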

Results

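Gene expression was measured by RNA sequencing in 12 samples of equine amniotic membrane, 6 with induced placentitis and 6 negative controls. Total counts per library were 33658479 to 52735202 in controls and 33095353 to 56372634 in placentitis, and 18310 to 19211 genes were detected per library. The most abundant transcripts were those of matrix-producing cells. COL1A1, a chain of type I collagen, took 4.71% of all counts, FN1 (fibronectin) 3.28% and COL1A2 2.23%, followed among named protein-coding genes by the foetal growth factor gene IGF2 with 1.42%. The 10 most abundant rows of the table held 22.2% ± 2.63 of the counts in controls and 18.5% ± 3.31 in placentitis (exact permutation p = 0.0476, two-sided, not adjusted). Mitochondrially encoded transcripts held 2.12% ± 0.712 and 1.62% ± 0.413 (exact permutation p = 0.173), and 18S ribosomal RNA 0.377% ± 0.122 and 0.41% ± 0.156 (exact permutation p = 0.697).

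The largest difference between libraries was not between the groups. Control 6, placentitis 3 and placentitis 4 stood apart on the first principal component, at 112.8, 111.5 and 84.3, while the other libraries lay between -64.1 and -16.6. The component held 33.7% of the variance. Its positive end was led by smooth muscle and endothelial genes such as ACTG2, MYH11, MCAM and PECAM1, and its negative end by epithelial genes such as KRT4 and FOXA1. The vascular score was 5.79, 5.53 and 6.18 in these 3 libraries, 3.97 in control 3, 3.13 in placentitis 5 and 0.78 to 2.39 in the others. The amniotic epithelium score was 2.86, 3.31 and 3.58 in the 3 libraries and 4.82 to 6.67 in the others. VWF, the endothelial von Willebrand factor, had 151, 113 and 244 CPM in the 3 libraries, against 73.5 in control 3 and 0.945 to 21.1 in the others. Group means differed on the second component, which held 13.9% of the variance. Controls lay at -31.7 ± 24.7 and placentitis at 31.8 ± 25.1 (n = 6 each, exact permutation p = 0.00433, not adjusted). No test of the components or of the other library measures was planned. The groups overlapped on the second component, with placentitis 4 at -10.9 and control 1 at 10.6. SAA1, MMP9, TREM1, SOD2, IL1B and LCN2 were among the genes at its positive end. So were JAK1 and ARHGEF7, and EIF4G1 stood at the negative end, 3 genes whose counts fall to 0 in some libraries.

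**Figure D1:**
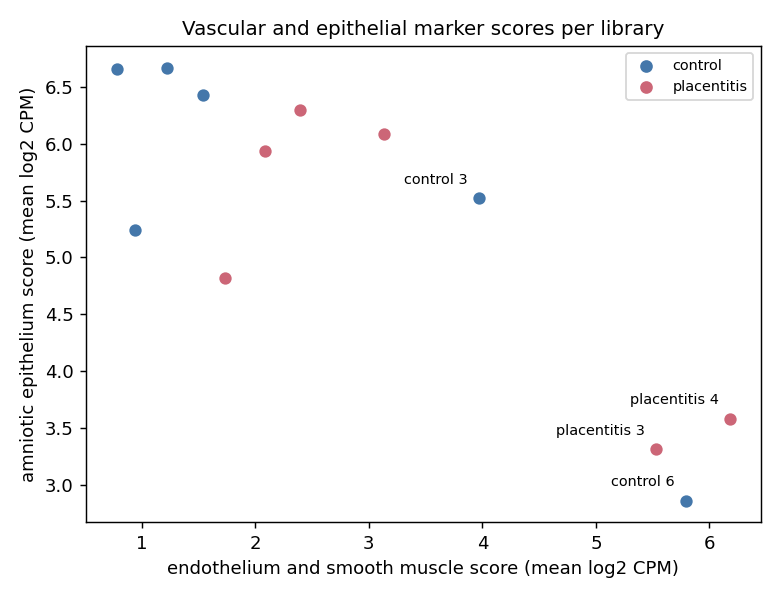
Vascular score against amniotic epithelium score of each library, both as mean log2 CPM of the tested members, with controls and placentitis libraries marked. Control 6, placentitis 3 and placentitis 4 combine the highest vascular scores (5.53 to 6.18) with the lowest epithelial scores (2.86 to 3.58).

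The main comparison asked which transcripts of the amniotic membrane differ in ascending placentitis from uninfected controls. No single gene passed the threshold over all genes with edgeR, while 12 of 38 gene lists, among them those of inflammation and of hypoxia, were higher in placentitis by camera with a preset correlation and 0 with an estimated correlation. IL1B, the gene of the cytokine interleukin-1 beta, was at 1.14 ± 0.722 CPM in controls and 13.5 ± 10.9 CPM in placentitis (n = 6 each), an 11.8-fold difference. AOAH, which codes for an enzyme that removes acyl chains from bacterial lipopolysaccharide, was at 2.69 ± 1.46 and 13.1 ± 2.76 CPM. HMGN3, a nucleosome-binding protein gene, was at 23.4 ± 3.95 CPM in controls and 11.8 ± 1.69 CPM in placentitis.

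With edgeR, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.0636. At an unadjusted p under 0.05, 1073 genes were higher and 899 lower, where 816 in both directions together are expected by chance. DESeq2 called 224 genes higher and 101 lower, 127 and 38 of them with an absolute log2 fold change over 1, and limma-voom with quality weights called 10 and 4. Of the 325 genes DESeq2 called, 321 were tested in edgeR, and all 321 had the same direction and an unadjusted p under 0.05 there. Without placentitis 4, edgeR called 19 genes higher and 9 lower, among them IL1B, SOD2, BNIP3 and AOAH; without control 1 it called 2 higher (IL2RG and SLAMF8) and without control 3 it called 1 higher (AOAH). Without the 3 libraries rich in vascular transcripts edgeR called LCN2 alone, within the samples whose identifier starts with O it called 3 genes higher and 0 lower, and with that letter as a term 2 higher and 1 lower (ELOA, MVP and PLXNA3).

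The 5 genes in each direction with the smallest p did not pass. In all 10, which were picked by their p-values, the 6 placentitis libraries lay beyond every control. Over all 16327 genes the groups were apart in this way in 163, where chance gives about 35 on average. The 99 other splits of the same libraries that were drawn gave a median of 24 and a highest count of 162. Besides AOAH (log2 fold change 2.28 ± 0.33 SE, adjusted p = 0.0636, edgeR) and IL1B (3.56 ± 0.61, adjusted p = 0.112), the higher genes were CD38, an NAD-consuming surface enzyme of activated leukocytes (2.21 ± 0.39), AKAP1, which anchors protein kinase A at mitochondria (1.29 ± 0.22), and TMEM186 (0.64 ± 0.11), each with an adjusted p = 0.112. The lower genes were FAM129C, at 13.8 ± 1.58 CPM in controls and 6.86 ± 1.12 in placentitis, and HMGN3 (-0.99 ± 0.14), both with an adjusted p = 0.0636, CARNS1, which makes carnosine (-0.89 ± 0.14, adjusted p = 0.0886), PAMR1 (-1.11 ± 0.19, adjusted p = 0.112) and the zinc finger gene ZNF521 (-0.74 ± 0.14, adjusted p = 0.132).

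**Figure D2:**
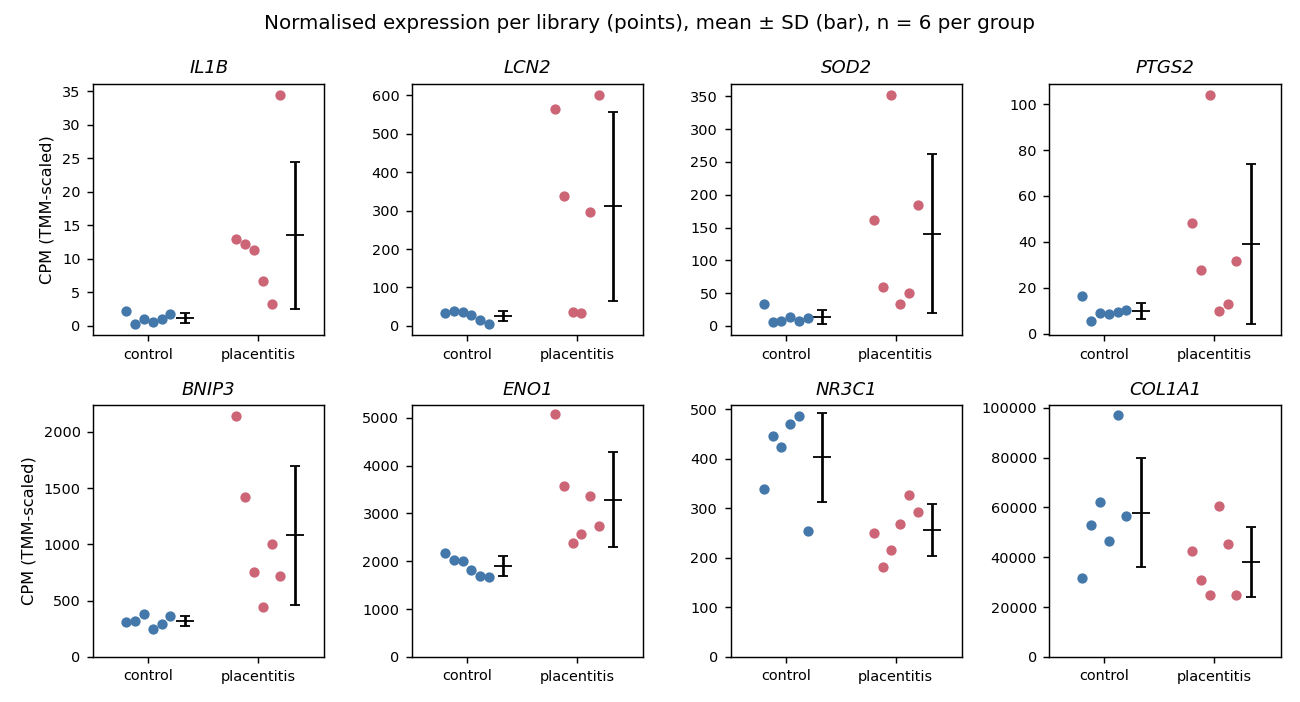
CPM of 8 genes in each library on a linear scale, with the mean and SD of each group. IL1B lies between 3.25 and 34.4 CPM in placentitis and between 0.306 and 2.25 CPM in controls, and LCN2 stays within the control range in placentitis 3 and 4.

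Genes of innate immunity and inflammation formed 8 of the 12 groups that were higher. These lists share members and are not separate evidence. Complement and macrophages share C1QA, C1QB, C1QC and VSIG4, and cytokines and inflammasome share IL1B and IL18. The macrophage list also shares CD14 with NF-kappaB signalling and CD86 with antigen presentation, and the antimicrobial and neutrophil lists share LCN2 and others. Of 38 lists tested with camera at a preset correlation, 12 were higher and 3 lower in placentitis. With an estimated correlation 0 passed (lowest adjusted p = 0.401 with an estimated correlation; 4 lists had an unadjusted p under 0.05). The exact permutation of list scores also passed 0 lists, with a lowest adjusted p = 0.0823 and 9 lists at an unadjusted p under 0.05. By fry 0 lists passed in the directional form (lowest adjusted p = 0.113) and 7 in the mixed form (lowest adjusted p = 0.000737). No member of any list passed over all genes tested with edgeR. Most of these lists did not part the groups by score. Placentitis libraries above every control numbered 5 for cytokines, NF-kappaB signalling and antimicrobial genes. They numbered 3 for complement, 2 for the inflammasome and for oxidative stress, and 1 for antigen presentation. Control 1 scored 5.14 for macrophages and 2.38 for neutrophils, where placentitis ran from 3.48 to 5.17 and from 1.33 to 3.81. Within the samples whose identifier starts with O, camera with a preset correlation called 9 of the 12 higher and 2 of the 3 lower lists.

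The inflammatory cytokine list had a score 0.96 higher in placentitis (1.78 ± 0.55 against 0.82 ± 0.36 log2 CPM, n = 6 each), with 5 of 6 placentitis libraries above every control (camera adjusted p = 0.00121; adjusted p = 0.423 with an estimated correlation). Of its 19 tested members, 4 passed when adjusted over the list alone and 0 over all genes: IL1B, CSF1, IL1R2 and PTX3. CSF1, a growth factor of macrophages, was at 68.3 ± 14.4 CPM in controls and 136 ± 35.7 in placentitis, and IL1R2, a decoy receptor for interleukin-1, at 0.479 ± 0.479 and 2.78 ± 1.66. PTX3, a secreted pattern recognition protein, reached 280 CPM in placentitis 3 and 0.626 to 12.1 in the other placentitis libraries; its log2 fold change of 6.37 ± 1.61 was 2.75 without placentitis 3. TNFSF10, the member with the highest expression, was at 132 ± 42.7 and 117 ± 62 CPM.

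Signalling through NF-kappaB and Toll-like receptors, which detect bacterial products, had 26 of 33 tested members with a positive difference (score 0.54 higher, camera adjusted p = 7.21e-05; adjusted p = 0.401 with an estimated correlation). None of them passed when adjusted over the list alone (0 of 33, edgeR), and 8 were higher and 0 lower at an unadjusted p under 0.05. DESeq2 called CD14 among them. NFKB2 was at 75.9 ± 20.9 CPM in controls and 116 ± 20.6 in placentitis, NFKBIA at 98.7 ± 40.2 and 158 ± 79.9, RELA at 118 ± 8.42 and 134 ± 8.12, and TNFAIP3, an inhibitor of the pathway, at 7.10 ± 3.63 and 16.5 ± 4.45. The inflammasome and pyroptosis list was higher by 0.87 (camera adjusted p = 0.000761; adjusted p = 0.477 with an estimated correlation), with 2 of 11 members past the threshold adjusted over the list alone, IL1B and CASP4, the latter at 41.9 ± 5.72 and 64.8 ± 24.3 CPM. The log2 fold change of CASP4 was 0.63 ± 0.20, and 0.41 without placentitis 6. GSDMD, the pore-forming gasdermin D, was at 44.0 ± 7.41 and 51.2 ± 9.92 CPM.

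Antimicrobial genes showed the largest difference of these scores, 1.61 (4.24 ± 0.79 in placentitis, 2.62 ± 0.91 in controls). The difference was positive in 8 of 8 tested members (camera adjusted p = 0.00209, and adjusted p = 0.401 with an estimated correlation). The list names 24 genes, of which 17 are in the table, so most of it was not tested. Within the samples whose identifier starts with O the difference was 1.23 (camera adjusted p = 0.0751). There the low-count filter was applied again, which can change the members tested. Over the same 8 members placentitis was 2.11 above the controls with O (n = 2), and the letter as a term also gave 2.11 (camera adjusted p = 0.00579). LCN2, whose protein binds bacterial siderophores, RNASE4 and SAA1 passed when adjusted over the list alone. LCN2 was at 26.5 ± 13.2 CPM in controls and 311 ± 246 in placentitis, but at 33.2 and 35.6 CPM in placentitis 4 and 3. SAA1, the acute phase protein serum amyloid A, had 94.7 CPM in placentitis 3 and 0.166 to 8.06 in the other placentitis libraries; its log2 fold change of 5.61 ± 1.77 was 2.74 without placentitis 3. RNASE4 was at 147 ± 32.3 and 234 ± 89.7 CPM.

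The complement list was higher by 0.73 (17 of 20 members positive, 0 past the threshold adjusted over the list alone or over all genes, and 3 higher at an unadjusted p under 0.05 with edgeR; DESeq2 called 0). Its camera adjusted p was 0.00185 (adjusted p = 0.481 with an estimated correlation), and without the 3 libraries rich in vascular transcripts the difference was 0.46 (camera adjusted p = 0.164). C1S was at 93.0 ± 51.3 and 202 ± 169 CPM and C4BPA at 88.9 ± 66.4 and 125 ± 74.0. Antigen processing and presentation was higher by 0.38 (camera adjusted p = 0.00448; adjusted p = 0.481 with an estimated correlation), and CD40 was its only member past the threshold when adjusted over the list alone. CD74, the invariant chain of class II molecules, was at 621 ± 343 and 751 ± 249 CPM, and the protease gene CTSS at 246 ± 100.4 and 454 ± 196.

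Among the markers of leukocytes, neutrophil genes were higher by 1.14 (camera adjusted p = 0.0042; adjusted p = 0.481 with an estimated correlation). LCN2, MMP9, TREM1 and NCF1, 4 of 13 tested members, passed when adjusted over the list alone, and 0 over all genes. MMP9, the gelatinase of neutrophil granules, had 685 and 617 CPM in placentitis 1 and 6, and 1.76 to 50.0 in the other placentitis libraries, against 8.24 ± 6.30 in controls. TREM1, an activating receptor of neutrophils and monocytes, was at 0.528 ± 0.673 and 5.27 ± 5.86 CPM, and AQP9 at 155 ± 87.6 and 86.2 ± 63.5. AQP9 had 4.07, 2.26 and 15.5 CPM in control 6, placentitis 3 and placentitis 4, the libraries low in epithelial transcripts, and 93.4 to 277 in the others. LCN2 was also lowest of its group in these libraries, at 5.65, 35.6 and 33.2 CPM. Whether these members measure neutrophils here was not tested. LCN2 also stands in the antimicrobial list and AQP9 in the aquaporin list. Markers of monocytes and macrophages were higher by 0.70 (16 of 18 positive, camera adjusted p = 0.000537; adjusted p = 0.487 with an estimated correlation), and by 0.41 without the 3 libraries rich in vascular transcripts (camera adjusted p = 0.109). CSF1R was at 71.3 ± 32 and 106 ± 53.3 CPM and STAB1 at 123 ± 44.0 and 154 ± 87.2. None of the macrophage members passed when adjusted over the list alone (0 with edgeR, 4 higher at an unadjusted p under 0.05, CD14 called by DESeq2).

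Chemokine genes were less uniform. For chemokines of monocytes and lymphocytes the camera adjusted p was 0.0603, with CCL2, CCL8 and CCL3 past the threshold when adjusted over the list alone. CCL2, which attracts monocytes, was at 57.0 ± 33.8 CPM in controls and 213 ± 219 in placentitis, with 641 CPM in placentitis 6, and its log2 fold change of 1.90 ± 0.59 was 1.18 without placentitis 6. That of CCL8, 2.01 ± 0.61, was 1.21 without the same library. CXCL16 was at 101 ± 44.5 and 145 ± 48.4 CPM. The neutrophil chemokines did not pass (camera adjusted p = 0.642): the mean log2 fold change of the 4 tested members was -0.17 and the median 0.25, with a test direction of higher. Their score difference was 0.22 in all libraries, 1.75 within the samples whose identifier starts with O (camera adjusted p = 0.0444) and 1.74 with the letter as a term (camera adjusted p = 0.0673), and all libraries gave an adjusted p = 0.846 with an estimated correlation. CXCL8 was at 31.1 ± 29.7 and 41.7 ± 49.6 CPM. Interferon-stimulated genes had a score of 4.20 ± 0.42 in controls and 4.23 ± 0.67 in placentitis (camera adjusted p = 0.712).

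**Figure D3:**
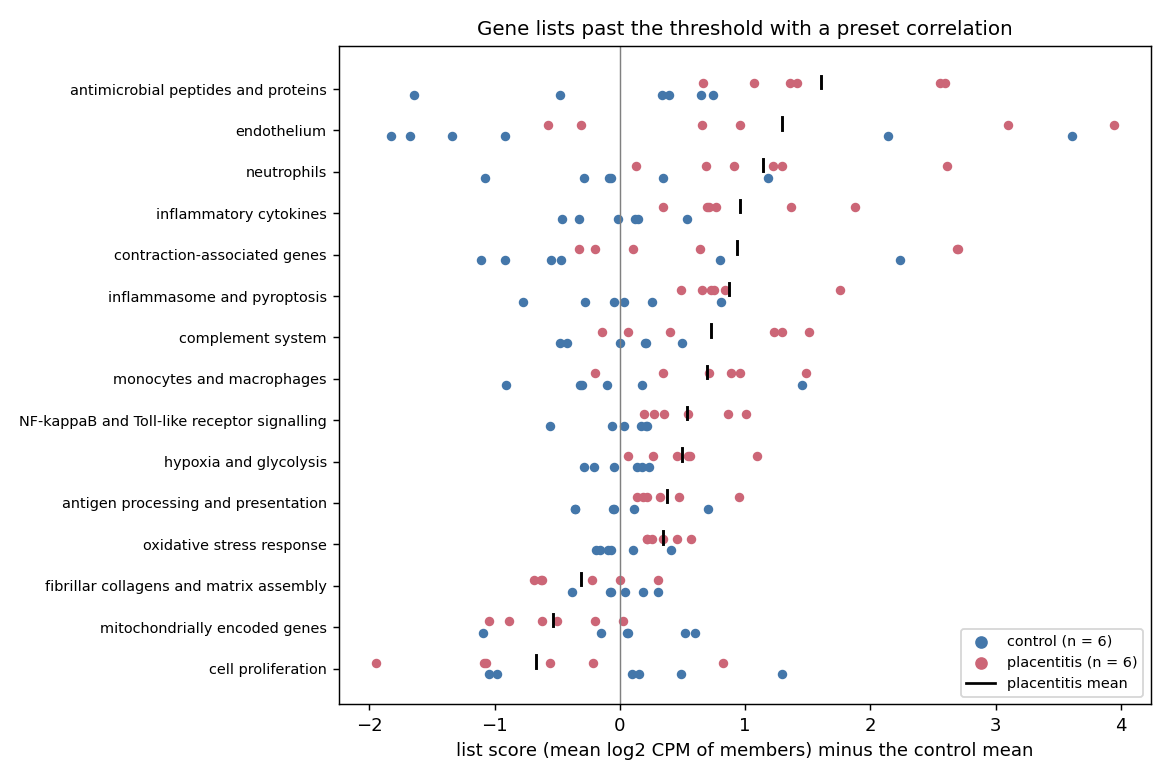
Score of each of the 15 lists that passed with a preset correlation, per library, as mean log2 CPM minus the mean of the 6 controls. In the hypoxia and glycolysis list and the inflammatory cytokine list 5 of 6 placentitis libraries lie above every control. In the antigen presentation list 1 of 6 does, and in the inflammasome and oxidative stress lists 2 of 6 do.

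Transcripts of the hypoxia response and of glycolysis were higher in placentitis, by 0.50 in the score (8.03 ± 0.35 against 7.54 ± 0.22 log2 CPM), with 5 of 6 placentitis libraries above every control. This list had the smallest camera adjusted p of all, 9.75e-10 (adjusted p = 0.401 with an estimated correlation; exact permutation p = 0.013, adjusted 0.0987). A positive difference was found in 30 of 32 tested members, 8 passed when adjusted over the list alone, 0 passed over all genes, and DESeq2 called 7. BNIP3, a mitophagy receptor gene induced by hypoxia, was at 318 ± 46.7 CPM in controls and 1078 ± 614 in placentitis (log2 fold change 1.76 ± 0.32, edgeR adjusted p = 0.119 over all genes). ENO1 and ENO2, the enolases of glycolysis, were at 1896 ± 206 and 3290 ± 996 CPM and at 78.8 ± 34.4 and 205 ± 81.5 CPM. EGLN1, an oxygen-sensing prolyl hydroxylase gene, was at 64.8 ± 6.72 and 109 ± 28.2 CPM, SLC16A3, which exports lactate, at 173 ± 12.6 and 279 ± 63.5, and GAPDH at 1979 ± 280.0 and 2871 ± 1004.

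The oxidative stress list was higher by 0.35 (camera adjusted p = 0.00631; adjusted p = 0.481 with an estimated correlation), with SOD2, HMOX1 and PRDX4 past the threshold adjusted over the list alone. SOD2, the mitochondrial superoxide dismutase, was at 13.6 ± 10.1 and 141 ± 121 CPM, a 10.4-fold difference, with all placentitis libraries above every control. HMOX1, heme oxygenase 1, was at 16.4 ± 12.7 and 47.4 ± 20.1 CPM, PRDX4 at 166 ± 18.9 and 231 ± 42.8, and PRDX1 at 159 ± 37.2 and 202 ± 31.8. Mitochondrially encoded genes had a negative difference in 12 of 12 tested members (score -0.53, camera adjusted p = 0.00209; adjusted p = 0.487 with an estimated correlation). Without the 3 libraries rich in vascular transcripts the score difference was -0.47 (camera adjusted p = 0.0727), close to that in all libraries. ATP8 was at 4416 ± 2229 and 2785 ± 938 CPM and COX1 at 7994 ± 2202 and 6853 ± 1679, and 0 members passed when adjusted over the list alone with edgeR, 5 were lower at an unadjusted p under 0.05 and DESeq2 called 0. Nuclear-encoded oxidative phosphorylation genes had a camera adjusted p of 0.0639 and a score difference of 0.08. Within the samples with O the difference was 0.22 (camera adjusted p = 0.00122) and with the letter as a term 0.21 (camera adjusted p = 0.000734), while all libraries gave an adjusted p = 0.61 with an estimated correlation and 0.365 by fry. NDUFV2 was past the threshold when adjusted over the list alone. In the unfolded protein response list (camera adjusted p = 0.445) TRIB3, a stress-induced pseudokinase gene, passed when adjusted over the list alone, at 2.64 ± 0.348 and 19.6 ± 22 CPM. In the apoptosis list (camera adjusted p = 0.0603) CASP3 did, at 17.3 ± 2.49 and 24.8 ± 3.67 CPM, and TNFRSF1A was at 124 ± 24.4 and 188 ± 50.7.

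Genes of prostaglandin synthesis and signalling went both ways, with 12 of 20 positive and 8 negative. The list did not pass with camera (adjusted p = 0.113), and did in fry's mixed form (adjusted p = 0.00232), which tests for change in either direction. PTGS2, the inducible cyclooxygenase, was at 9.79 ± 3.5 CPM in controls and 39.0 ± 34.8 in placentitis. PTGES, the prostaglandin E synthase, was at 44.5 ± 11.8 and 114 ± 52.1 CPM, and PTGIR, the prostacyclin receptor, at 1.58 ± 0.947 and 4.34 ± 2.16. These 3 passed when adjusted over the list alone. Steroid synthesis, metabolism and receptor genes did not pass as a list (score difference 0.03, camera adjusted p = 0.866). The glucocorticoid receptor gene NR3C1 was at 403 ± 89.8 and 256 ± 52.4 CPM (log2 fold change -0.65 ± 0.19, edgeR adjusted p = 0.231) and PGRMC1 at 136 ± 32.5 and 147 ± 23.6.

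Contraction-associated genes and endothelial markers also passed with camera. Both moved with the vascular score, which was largely fixed in advance, because 20 of their 27 tested members form that score. The contraction list was higher by 0.94 (4.88 ± 1.40 against 3.95 ± 1.28; adjusted p = 0.0157, and adjusted p = 0.481 with an estimated correlation), with PTGS2 as its member past the threshold adjusted over the list alone. ACTA2 had 572, 749 and 1120 CPM in control 6, placentitis 3 and placentitis 4 and 4.15 to 121 in the others, and GJA1, a gap junction gene, was at 892 ± 240 and 979 ± 240 CPM. The endothelium list was higher by 1.29 (2.11 ± 1.84 against 0.82 ± 2.30; adjusted p = 0.0157, and adjusted p = 0.61 with an estimated correlation), with 0 of 17 members past the threshold adjusted over the list alone with edgeR, 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2. VWF was at 38.8 ± 61.9 and 65.2 ± 97.3 CPM and FLT1 at 133 ± 130 and 138 ± 92.4. Without the 3 libraries rich in vascular transcripts the score differences were 0.51 and 0.91 (adjusted p = 0.171 for both lists), and within the samples with O the score differences were 0.06 and 0.31. The contraction list lost its call without control 2, placentitis 3 or placentitis 4 (highest adjusted p = 0.104), and the endothelium list without control 1, 2, 4 or 5 or placentitis 3 or 4 (highest adjusted p = 0.282). With each library left out in turn, the difference ran from 0.59 to 1.39 for contraction and from 0.77 to 2.02 for endothelium.

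Among the matrix lists only that of fibrillar collagens and matrix assembly passed, as lower. It had 25 of 30 members negative (score -0.31, camera adjusted p = 0.00217; adjusted p = 0.487 with an estimated correlation), with 0 past the threshold adjusted over the list alone with edgeR, 3 lower and 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2. COL1A1 was at 57890 ± 21960 CPM in controls and 38110 ± 14070 in placentitis, COL1A2 at 27620 ± 9307 and 18450 ± 9367, and FN1 at 33400 ± 13610 and 30170 ± 12480. Metalloproteinases and their inhibitors did not pass as a list (score difference 0.34, camera adjusted p = 0.206); TIMP2 was at 878 ± 221 and 1004 ± 240 CPM and MMP2 at 834 ± 166 and 600 ± 208. Basement membrane genes did not pass (score difference 0.05, camera adjusted p = 0.623). Proliferation genes had a negative difference in 24 of 28 members (score -0.67, 1.79 ± 0.94 against 2.46 ± 0.89; camera adjusted p = 0.0157, adjusted p = 0.69 with an estimated correlation), with 0 past the threshold adjusted over the list alone with edgeR, 2 lower and 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2. MCM7 was at 46.7 ± 10.5 and 53.9 ± 6.72 CPM and MCM6 at 38.9 ± 15.1 and 32.9 ± 3.91. That call was lost without control 2, control 3, placentitis 1 or placentitis 5, with differences of -0.58, -0.41, -0.42 and -0.59 (highest adjusted p = 0.492). The call was also lost within the samples whose identifier starts with O, where the difference was -0.79 (adjusted p = 0.0612). Without the 3 libraries rich in vascular transcripts it was -0.78 (adjusted p = 0.0599).

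Markers of the remaining cell types did not pass with camera in all 12 libraries, while several of these lists did in other fits. Amniotic epithelium had a score of 5.56 ± 1.45 in controls and 5.01 ± 1.32 in placentitis (adjusted p = 0.23), a difference of -0.56. Without control 6 it was -1.09 (camera adjusted p = 0.00166), and with the letter as a term 0.95 (camera adjusted p = 0.0464), while all libraries gave an adjusted p = 0.759 with an estimated correlation and 0.714 by fry. In that list KRT8 was at 959 ± 604 and 628 ± 509 CPM and 46.2 CPM in control 6. Keratinocyte differentiation was at 2.82 ± 1.18 and 2.82 ± 1.20 (adjusted p = 0.886, mean log2 fold change -0.03 and median 0.14). Fibroblasts and stroma were at 8.98 ± 0.28 and 8.65 ± 0.42 (adjusted p = 0.0603; adjusted p = 0.603 with an estimated correlation), a difference of -0.33. The list passed as lower with the vascular score as a term (-0.47, adjusted p = 0.00391), without the 3 libraries rich in vascular transcripts (-0.46, adjusted p = 0.0256), within the samples with O (-0.53, adjusted p = 0.0208) and with the letter as a term (-0.54, adjusted p = 0.0158). Smooth muscle and pericytes were at 4.26 ± 1.76 and 5.20 ± 1.99 (adjusted p = 0.194). The adjusted p was 0.118 for dendritic cells, 0.859 for T and natural killer cells, 0.588 for B and plasma cells, 0.311 for mast cells, basophils and eosinophils, and 0.302 for platelets and megakaryocytes. It was 0.595 for trophoblast of the adjoining chorioallantois and 0.302 for allantoic and other urogenital epithelium. Only 3 erythroid members were tested in all 12 libraries, so that list has no test there. Its score was -1.19 ± 0.98 and -1.27 ± 0.95. Among process and quality lists, aquaporins and amniotic fluid transport had an adjusted p of 0.194 and immediate early genes one of 0.053.

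The identifier letter was examined within the controls, since it runs with the groups in part. Controls with O (n = 2) were below those with K or L (n = 4) in amniotic epithelium (mean score 4.05 and 6.32). There control 5 lay at 5.24 and control 6 at 2.86, and the controls with K or L at 5.52 to 6.67. In endothelium the 2 lay at -0.86 (control 5) and 4.43 (control 6, 1 of the 3 libraries rich in vascular transcripts), and the others at -1.01 to 2.96. In edgeR 1 gene, EXD2, was lower and 0 were higher with O (17509 genes tested; 1013 higher and 1133 lower at an unadjusted p under 0.05). EXD2 had 0 CPM in the O controls, 11.7 in the others and 7.34 in placentitis, and was chosen after its values were seen. The counts rested on single libraries, and without control 1, 3 or 4, 0 were lower. Without control 5, 134 genes were higher and 607 lower, but there the O side is control 6 alone, which is rich in vascular transcripts, and all the spread comes from the controls with K or L. No K or L sample has placentitis, so the letter could be separated from the disease only through the 2 controls with O.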

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

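In this part, the tests of the identifier letter, of the vascular share, of the 3 libraries rich in vascular transcripts and of genes near 0 in single libraries were chosen only after the result was seen, and so was the count over splits of genes in which the groups do not overlap, while the test of leukocytes and the other counts over splits were not.

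Of 246 groups of 6 values that were examined, 21 held a highest or lowest library that stood apart from the other 5 by Dixon's ratio of gap to range, where chance gives about 12. Control 6 accounted for 9 of them and is 1 of the 3 libraries rich in vascular transcripts. It was lowest among controls in the scores of amniotic epithelium (2.86), allantoic and other urogenital epithelium (2.08) and aquaporins and fluid transport (2.06), and in the log2 CPM of KRT8 (5.53), PGRMC1 (6.27) and AQP9 (2.04). It was highest in NFKB2 (6.87), TNFRSF1A (7.44) and the share of globin transcripts, 0.001076%. Placentitis 6 was highest of its group in the scores of the inflammasome list (3.75), prostaglandin genes (3.87) and steroid genes (3.41) and in CASP4 (6.81). Control 5 was lowest in NF-kappaB and Toll-like receptor signalling (2.69) and in NFKBIA (4.97). Placentitis 3 was highest in CTSS (9.73) and TNFRSF1A (8.17), placentitis 1 in PRDX4 (8.29) and STC1 (5.11), and control 1 in SLAMF8 (1.94), while placentitis 5 was lowest in CD74 (8.32).

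Camera with a preset correlation called 12 lists higher in placentitis (0 with an estimated correlation, lowest adjusted p = 0.401 with an estimated correlation). Of these, 10 kept their calls with the vascular score as a term and with the identifier letter as a term. Without the 3 libraries rich in vascular transcripts 8 kept theirs. Complement (0.73, SE 0.33, to 0.45, SE 0.35, on scores scaled over all 12 libraries) and macrophages (0.70, SE 0.40, to 0.40, SE 0.49) also lost their calls there. Their differences shrank and fewer libraries were left, and the cause of the lost calls was not tested. With the vascular score as a term the differences were 0.55 for complement (camera adjusted p = 0.0395) and 0.78 for macrophages (camera adjusted p = 0.00107). The mean score difference of these 10 went from 0.78 (SE 0.23) to 0.76 (SE 0.25) with the vascular score, to 0.73 (SE 0.30) without the 3 libraries and to 1.08 (SE 0.31) with the letter (hypoxia 0.50 to 0.74, NF-kappaB 0.54 to 0.80, macrophages 0.70 to 1.32), while amniotic epithelium moved from -0.56 to 0.11 and 0.95, which argues against the share of vascular tissue and against a letter effect as the whole source of the 10, though a part of complement and macrophages is left open and the letter rests on only 2 controls with O. For contraction and endothelium the mean difference of 1.12 (SE 0.98) shrank to 0.14 (SE 0.06) and 0.19 (SE 1.39), which ended both calls, and neither source can be told apart from placentitis there, because 20 of their 27 members form the vascular score and the letter's own coefficient of 1.39 has an SE of 1.48. For the hypoxia and glycolysis list, a term for the mean of the neutrophil and macrophage scores left a difference of 0.47 of 0.50 (SE 0.22, camera adjusted p = 2.93e-08 with a preset correlation). The difference was thus not taken up by this score. Leukocytes as its source are left open, because the SE is wide and the score measures leukocytes imprecisely. It includes LCN2 and AQP9, which were lowest of their groups in the libraries low in epithelial transcripts. Chance was not excluded for the number of lists, since 17 of 100 splits of the libraries gave 15 or more (1 of the 16 others kept the controls with K or L together, with 15) and the highest other split gave 20, so an inflammatory and hypoxic response of the membrane to infection is a hypothesis that these data are consistent with and do not settle.

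Control 6, placentitis 3 and placentitis 4 combined high vascular with low epithelial transcripts. In total counts, mitochondrial share and 18S share at most 1 of the 3 lay outside the range of the other 9 on 1 side. This argues against depth as their shared source. RNA integrity was not examined, so RNA quality is left open. A piece of membrane with less epithelium, or with adjoining vascular tissue, is a candidate explanation: 85% of the amniotic epithelium members (17 of 20) lay below the median of the other 9 libraries in all 3, while the stromal score was 9.10 against 8.72 ± 0.36. Placentitis cannot be told apart as a source, since 2 of the 3 libraries are placentitis and the vascular score over all 12 differed by 1.13 (SE 1.14, exact permutation p = 0.331). The test of epithelial members is partly circular, because the libraries were picked on a component that epithelial genes help to form, and how the tissue was sampled is not given in the sources used here.

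Some abundant genes had almost no counts in single libraries: of 8776 with a median count of at least 500, 55 fell under 2% of their own median CPM in a library, and 24 of these did so in a library other than the 3 rich in vascular transcripts. Of those 24, 16 had another row of the table that was high where they were low, against at most 9 in 100 shuffles (median 5). Reads given to 1 or the other of 2 overlapping entries could give such pairs. The search ignored position, and the shuffles removed the differences between libraries that genes share. Some pairs were of 2 named genes, such as JAK1 and ATF3 or VCAM1 and PTPN14, and how many of the 16 are swaps was not tested. The pair of FOXN3 and LOC111770381 and that of EIF4G1 and LOC111769142 were each counted from both sides. EIF4G1, for example, was at 168 CPM in control 1 and 0 in placentitis 6, while LOC111769142 was at 0.16 and 134. The share of vascular tissue cannot be told apart as the source for the rest, since 56.4% of the 55 were near 0 in those 3 libraries alone and many of these are epithelial genes. Gene positions and the counting settings are not given in the sources used here, and a genetic variant between animals was not tested.

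Other splits of the 12 libraries into 6 and 6 were counted for each count of calls. Every split gives at least edgeR's 0 genes (100 of 100, highest other 15), so that count says nothing about chance. For its 1972 genes at an unadjusted p under 0.05, 3 of 100 splits gave as many, the real one included (highest other 2214), a share under 0.05. The share was also under 0.05 for limma-voom's 14 genes (1 of 100 splits, highest other 2) and for fry's 7 lists in the mixed form (2 of 100, highest other 8). So it was for the 163 genes in which the groups do not overlap (1 of 100), where the highest other split was close with 162. For the 325 genes of DESeq2 the share was not under 0.05, with 5 of 80 splits and a highest other of 376. These shares were not adjusted for the number of counts examined, and only a part of the 462 distinct splits was drawn. They therefore do not by themselves exclude chance. The split with 162 kept the 3 libraries rich in vascular transcripts together, as did each other split as large in edgeR's unadjusted counts (2 splits) and in DESeq2 (4 splits). The highest split that parted them gave 136, 1742 and 226 genes. That split and the 1 with 162 kept the 4 controls with K or L together, as the real split does, while the splits as large in unadjusted counts and in DESeq2 did not. These splits thus go with the vascular libraries, the identifier letter or both. A split that keeps the 4 controls together also shares at least these 4 of the 6 controls with the real split. Placentitis itself and a structure of the samples therefore cannot be told apart as the source of its counts. How far the other large splits overlap with the real groups was not examined.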

How the results depend on the processing

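In this part the fits without the 3 libraries rich in vascular transcripts, with the vascular score as a term, by DESeq2 with the letter or without those 3 libraries, the list tests with the letter as a term and the fit without genes near 0 in single libraries were chosen only after the result was seen. No paired analysis was possible because each identifier occurs once and the groups share no replicate numbers. Unless a value shows it, the cause of a change was not tested. Each library holds at least 33095353 counts, so depth limits chiefly genes of low expression such as CCL3 and IL1R2.

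The counts of genes stayed at 0 higher and 0 lower in edgeR with DESeq2 size factors, upper-quartile scaling, no filter, the stricter filter, dispersion without the robust option, and without the genes near 0 in single libraries (lowest adjusted p = 0.0572 to 0.107). DESeq2 called 224 higher and 101 lower, of which 127 and 38 had an absolute log2 fold change over 1. DESeq2 with the letter as a term called 369 and 250 (219 and 117 over 1), of which 134 were among the 325 called without it, so most of the 325 were lost. Without the 3 libraries it called 443 and 339 (203 and 148 over 1), with 257 of the 325. Limma-voom called 10 and 4 (8 and 3 over 1), a surrogate variable 2 and 2 (AOAH, CARNS1, HMGN3 and LCN2; 2 and 1 over 1) and the letter as a term 2 and 1 (2 and 1 over 1). Within letter O edgeR called 3 and 0 (ELOA, LOC100054251 and an unnamed RNA; 3 over 1), without the 3 libraries 1 and 0 (1 over 1), and with the vascular score as a term 0 and 1 (HMGN3; 1 over 1). None of the 3 genes called within O was called by DESeq2 on all libraries. Leaving out a library gave 0 to 19 genes higher and 0 to 9 lower (0 to 16 and 0 to 4 over 1).

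For the lists, 12 higher and 3 lower became 0 and 0 with an estimated correlation, and 0 and 0 with fry in its directional form. Leaving out a library gave 10 to 15 lists higher and 2 to 7 lower, with 7 lower without control 6 and 5 without placentitis 2, 3 or 6. List scores passed 0 lists under DESeq2 size factors and without the 3 libraries as well (6 to 9 lists at an unadjusted p under 0.05, exact permutation). Among the 15 lists that passed, no score difference changed sign. Over 78 genes and 1163 pairs of gene and setting, fits with a single library left out not counted, 23 changed sign and 125 came to pass the threshold; none had passed in edgeR with all libraries, so none could cease to.

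The genes that changed sign had not passed. With letter O only, the log2 fold change was 0.91 for KRT8, -0.23 for VWF, 0.27 for FN1 and 0.19 for AQP9, and with the letter as a term 0.90, -0.23, 0.27 and 0.18. DESeq2 with the letter gave 0.88 for KRT8, -0.22 for VWF, 0.26 for FN1 and 0.16 for AQP9. A surrogate variable gave -0.37 for VWF, -0.48 for ACTA2 and 0.14 for FN1, the vascular score -0.36 for VWF, -0.99 for ACTA2 and 0.22 for FN1. Without the 3 libraries VWF was at -0.93 and ACTA2 at -1.13, and with DESeq2 at -0.94 and -1.14. CXCL8 was at -0.03 with limma-voom. Leaving out a library gave -0.35 to 0.03 for TNFSF10, -0.35 to 0.82 for CXCL8, -0.40 to 2 for VWF, -0.31 to 0.75 for FLT1 and -0.31 to 0.05 for FN1.

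Lists that changed sign had not passed either. Within letter O the score difference was 0.00 for interferon-stimulated genes, 0.69 for aquaporins, 0.99 for keratinocyte differentiation, 0.38 for immediate early genes, 0.98 for amniotic epithelium, -0.08 for smooth muscle, -0.03 for dendritic cells, 0.00 for B and plasma cells, -0.03 for platelets and 0.94 for allantoic epithelium. The letter as a term gave 0.64 for aquaporins, 1.03 for keratinocyte differentiation, 0.37 for immediate early genes, 0.95 for amniotic epithelium (camera adjusted p = 0.0464), -0.09 for smooth muscle and 1.05 for allantoic epithelium. The vascular score as a term gave -0.08 for interferon-stimulated genes, 0.10 for aquaporins, 0.11 for keratinocyte differentiation, 0.11 for amniotic epithelium, -0.13 for smooth muscle, -0.01 for B and plasma cells and 0.23 for allantoic epithelium. The stricter filter gave -0.06 for steroid genes, -0.04 for basement membrane and 0.01 for keratinocyte differentiation, and without the 3 libraries steroid genes were at 0.00. Leaving out a library gave -0.17 to 0.62 for neutrophil chemokines, -0.19 to 0.16 for interferon-stimulated genes, -0.05 to 0.09 for steroid genes, -0.05 to 0.14 for basement membrane, -0.37 to 0.36 for keratinocyte differentiation, -0.02 to 0.16 for B and plasma cells and -1.16 to 0.00 for allantoic epithelium. Interferon-stimulated genes passed as lower without placentitis 6 (adjusted p = 0.0433).

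Some lists that did not pass in all libraries passed in other fits, all by camera with a preset correlation; with an estimated correlation none passed in all libraries. Within letter O these were neutrophil chemokines (1.75 against 0.22, adjusted p = 0.0444), nuclear-encoded oxidative phosphorylation (0.22 against 0.08, adjusted p = 0.00122), apoptosis (0.28 against 0.15, adjusted p = 0.0302), the unfolded protein response (0.37 against 0.12, adjusted p = 0.0422), steroid genes (0.34 against 0.03, adjusted p = 0.0438) and, as lower, fibroblasts and stroma (-0.53 against -0.33, adjusted p = 0.0208). The letter as a term called the same lists but the neutrophil chemokines (1.74, adjusted p = 0.0673), and also prostaglandin genes (0.57 against 0.36, adjusted p = 0.0439), monocyte and lymphocyte chemokines (0.86 against 0.60, adjusted p = 0.0328) and amniotic epithelium. Without control 6 amniotic epithelium (-1.09 against -0.56, adjusted p = 0.00166), allantoic epithelium (-1.16 against -0.56, adjusted p = 0.0237), aquaporins (-0.73 against -0.33, adjusted p = 0.00457) and immediate early genes (-0.64 against -0.45, adjusted p = 0.00325) were called lower, and smooth muscle (1.58 against 0.94, adjusted p = 0.00958) and dendritic cells (0.78 against 0.62, adjusted p = 0.0286) higher. Fibroblasts and stroma were called lower with the vascular score as a term and without the 3 libraries as well, and immediate early genes without the 3 libraries (-0.42 against -0.45, adjusted p = 0.042) and with the stricter filter (-0.44, adjusted p = 0.0435). Leaving out other libraries called immediate early genes, fibroblasts, the chemokines of monocytes and lymphocytes, apoptosis, oxidative phosphorylation, prostaglandin genes or aquaporins in some fits.

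Among controls, leaving out a library gave 0 to 134 genes higher and 0 to 607 lower with letter O, the highest without control 5, where the O side is control 6 alone and the spread comes only from the controls with K or L, and DESeq2 size factors gave 0 and 1.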

Other observations

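The genes in this part, and the look at altered names and at even counts, were chosen only after the result was seen; the test of the spread between libraries was not.

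Beyond the fixed lists, 6 genes picked by hand from those with small p-values are given here; none passed over all genes in edgeR, and no test asked whether they belong together. OSMR and IL4R, receptors of the cytokines oncostatin M and interleukin-4, were at 22.2 ± 5.74 and 97.5 ± 24.8 CPM in controls and at 58.8 ± 22.3 and 202 ± 38.7 CPM in placentitis (log2 fold change 1.40 ± 0.25 and 1.05 ± 0.18, both with an adjusted p = 0.112). SLAMF8, a surface protein gene of myeloid cells, was at 1.35 ± 1.21 and 7.91 ± 2.11 CPM, and NAMPT, which codes for an enzyme of NAD synthesis, at 32.2 ± 5.61 and 69.8 ± 23.4. STC1, a secreted glycoprotein gene that hypoxia induces, was at 1.26 ± 0.773 and 10.7 ± 11.8 CPM, with 34.4 CPM in placentitis 1. SESN2, a stress-induced sestrin, was at 10.5 ± 2.39 CPM in controls and 48.9 ± 37.7 in placentitis, from 14.7 CPM in placentitis 6 to 106 in placentitis 1. In all 6 genes every placentitis library lay above every control, which was so by the choice of genes. Over all 16327 genes the groups do not overlap in 163, against a median of 24 and a highest count of 162 in the 99 other splits drawn. DESeq2 called all 6, with adjusted p-values from 7.26e-06 for SLAMF8 to 0.000489 for SESN2, and limma-voom called SLAMF8 and OSMR.

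Among the 50 names with a non-breaking space, 42 were tested, and 1 looks like a member of the hypoxia and glycolysis list whose name, PGK1, had been turned into a number; this reading is a guess. Its log2 fold change was 0.50 ± 0.12 SE (edgeR adjusted p = 0.192), with 561.8 ± 53.1 CPM in controls and 793.4 ± 97.1 in placentitis, and 6 of 6 placentitis libraries lay above every control.

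The value 2 was 1.57 to 2.29 times as frequent among the counts of a library as the mean of the values 1 and 3, in controls and placentitis alike. How reads or read pairs were counted is not given in the sources used here.

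A hypothesis that placentitis libraries vary more from each other than controls was not borne out. The median log2 ratio of the SDs over genes was 0.102, and 280 of 462 splits gave a ratio as far from 0, with a largest of 0.5.

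The genes called between controls with and without the letter O changed with the control that was left out. Without control 2 the gene called lower with O was ARHGEF7, without control 3 LOC111770381 was called higher, and without control 6, where control 5 alone stands for O, EXD2 and PI3 were lower. ARHGEF7, EXD2 and LOC111770381 fall to about 0 CPM in some libraries: ARHGEF7 was at 39.3 CPM in control 1 and 0 in control 2, and LOC111770381 at 0.16 and 0.0834 in the same libraries but 122 in control 3.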
